A study of Mus musculus with 6 samples.

How the data were processed

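Gene expression was measured by RNA sequencing in primary mouse bone marrow-derived macrophages, which are macrophages grown in culture from marrow progenitors. The 6 libraries comprised 3 from cells with floxed Tmem175 alleles and Cre recombinase under the Lyz2 gene, called Tmem175 knockout here, and 3 from wild type cells. Per the labels' protocols, cells were lysed in TRIzol and libraries were made with a SMARTer mRNA kit. The design text speaks of separate wells and names no separate animals, so the p-values measure the spread between these wells, which may be technical.

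The deposited table holds raw counts per Ensembl gene, made by the authors with HISAT2 and featureCounts on GRCm38 per the submitters' processing notes. The tool versions, the annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping genes on opposite strands, and reads shared by near-identical genes, therefore cannot be told apart in these counts. The table lists 55421 genes. Symbols, biotypes and positions were taken from GENCODE M21 on the same genome build; 55154 IDs matched and 267 did not, and the unmatched IDs held 0.0315% to 0.0366% of the counts of a library.

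Total counts ranged from 24179548 to 31542741 per library. Counts were scaled by TMM and filtered with filterByExpr in edgeR 4.0.16 under R 4.3.3, which left 13588 genes. Knockout and wild type were compared with edgeR's two-sided quasi-likelihood test, with genotype as the only term and the package's default options. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the F statistic. Expression is given in CPM, the count of a gene relative to the scaled library total, after TMM scaling, as mean ± SD over 3 libraries per group, and coordinates are those of GENCODE M21. The common biological coefficient of variation was 0.0744.

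Before the data were examined, 37 gene lists were fixed, covering lysosomal, metabolic, immune and stress programmes, RNA quality and markers of other cell types of marrow. The list of sex-linked genes was not tested. The other 36 were tested with camera at a preset correlation of 0.01 (limma 3.58.1), adjusted over the 36 lists. Of 887 list entries, 883 matched a gene. Camera with an estimated correlation and fry were run as alternatives.

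Named genes were chosen by a rule fixed at the same time. It takes Tmem175 and Lyz2; the 10 largest changes in each direction among called protein-coding genes with a mean of at least 5 CPM and groups that do not overlap; the 10 smallest p-values not yet named; and up to 4 members with the smallest p from each list that passed its test or held at least 3 called genes. Genes named outside the rule are said to be so.

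The alternatives fixed at the same time were upper-quartile scaling, DESeq2 size factors, library totals, the DESeq2 1.42.0 Wald test, limma-voom, 3 other filters, an added fold change threshold, the replicate number as a block, and leaving out each library in turn. Alternatives for normalized values did not apply to counts. The DESeq2 test and the fold change threshold were not run for the gene lists. Added after the data had been seen were bias-corrected quasi-dispersions, a robust prior, 2 forms of reduced gene lists, a term for another split of the libraries and 1 surrogate variable from sva 3.50.0. Counts of called genes with the default and the bias-corrected dispersions had both been seen when the default was kept as the option the design fixed in advance implies. Sequence similarity between transcripts was searched with BLAST 2.17.0.

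The gene test was tested on simulated data for this comparison, in 5 sets of 13588 genes with 200 changed genes each. It recovered 63.6% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 98.8% of those changed 4-fold. The sets held far more changed genes than the 14 called in the real data, which eases the adjusted threshold. They also held no split of the libraries across genotype, so these shares may overstate recovery in the real data. Of 871 calls, 9.41% were false, above the nominal rate. No pair of libraries of a group agreed within sampling noise: the chi-square statistic over its degrees of freedom was 3.89 to 19.6.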

Results

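The data comprised 6 libraries of bone marrow-derived macrophages, 3 from Tmem175 knockout and 3 from wild type wells. TMEM175 is a potassium and proton channel of endosomes and lysosomes. The comparison set cells labelled Tmem175flox/flox Lyz2-Cre+/- against wild type cells. The 6 libraries include none with Cre or with floxed alleles alone. Loss of Tmem175 therefore cannot be told apart here from effects of Cre, its Lyz2 insertion or genetic background. Total counts were 31542741, 29118452 and 25979430 in the knockout and 24179548, 24547091 and 25916709 in the wild type libraries. Mitochondrially encoded genes took 1.19% ± 0.0470 of counts in knockout and 1.16% ± 0.0156 in wild type libraries (SD, n = 3 each). All libraries expressed Xist and had a count of 0 for Ddx3y, Eif2s3y, Kdm5d and Uty.

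Tmem175 (ENSMUSG00000013495, chromosome 5, 108629770 to 108648782) fell from 33.2 ± 0.318 CPM in wild type to 13.2 ± 1.13 CPM in knockout libraries (SD, n = 3 each). Its log2 fold change was -1.33 (SE 0.07, adjusted p = 6.01e-05, edgeR), and 39.8% of the wild type level remained. The knockout libraries stood at 14.3, 13.2 and 12.1 CPM and the wild type libraries at 32.8, 33.4 and 33.2 CPM. These are counts over the whole gene, and reads from exons outside the deleted part, or from cells without recombination, are not separated in them. Lyz2 (chromosome 10, 117277331 to 117282321), the lysozyme gene that carries the Cre insertion, fell from 45178 ± 4163 to 24326 ± 1578 CPM (SD, n = 3 each), a log2 fold change of -0.89 (SE 0.08, adjusted p = 0.00415, edgeR). It took 4.44% ± 0.355 of all counts in wild type and 2.47% ± 0.166 in knockout libraries (SD, n = 3 each).

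Beyond the targeted locus and the Cre locus, few genes separated the genotypes. In all, 12 genes were lower and 2 were higher in knockout macrophages at an adjusted p under 0.05. Vcam1, an adhesion molecule that binds integrins, showed the smallest p of the remaining genes: it fell from 30.1 ± 0.536 to 5.32 ± 1.33 CPM (SD, n = 3 each), a log2 fold change of -2.51 (SE 0.13, adjusted p = 6.01e-05, edgeR). Epb41l3, a membrane skeleton protein, fell from 7.43 ± 0.35 to 2.08 ± 0.502 CPM (log2 fold change -1.84, SE 0.17, adjusted p = 0.00512). Tmem175, Lyz2, Vcam1 and Epb41l3 were called in each of the 6 fits that left out 1 library.

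Several other genes that fell were expressed at low levels. Vsig4, a complement receptor of tissue-resident macrophages, had a log2 fold change of -2.28 (SE 0.32) and Timd4, a phosphatidylserine receptor used in the uptake of dying cells, one of -2.58 (SE 0.33). Itgad, an integrin alpha chain of leukocytes, had a log2 fold change of -3.34 (SE 0.41), with counts of 13, 2 and 16 in knockout against 82, 90 and 96 in wild type libraries. Paqr9, a progestin and adipoQ receptor family member, had one of -3.60 (SE 0.42), with counts of 2, 2 and 4 against 32, 22 and 31. Rims3, known from synaptic vesicle release, had one of -1.38 (SE 0.18). Their adjusted p-values ran from 0.0188 for Paqr9 to 0.0411 for Vsig4. None of Paqr9, Timd4, Rims3 and Vsig4 was called in any of the 6 fits without 1 library, where the lowest count of genes lower in knockout was 4 and the highest was 10. Itgad was called in 2 of those 6 fits. With the replicate block, Rims3 (adjusted p = 0.056) and Vsig4 (0.061) were not called.

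**Figure D1:**
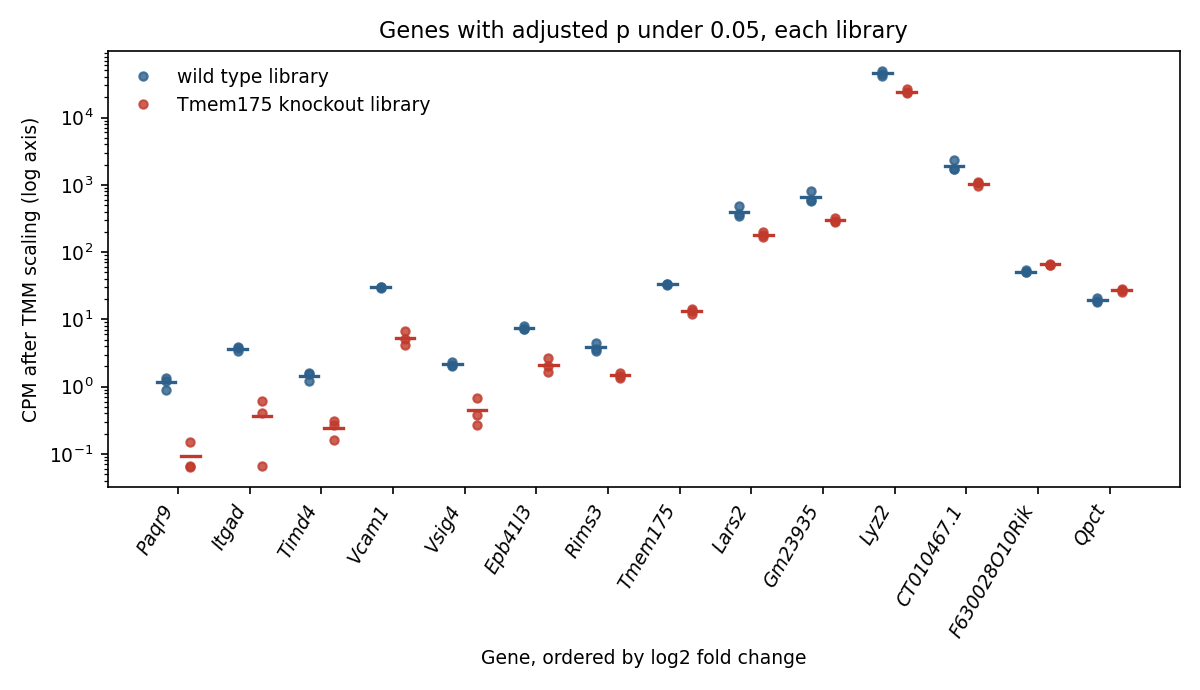
Expression of the 14 genes with adjusted p under 0.05 in each library, in CPM after TMM scaling on a log axis; points are libraries and horizontal lines are group means (n = 3). Vcam1 stood at 5.32 CPM on average in knockout against 30.1 in wild type, and Tmem175 at 13.2 against 33.2.

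A ribosomal RNA gene, Lars2 and Gm23935 made up a further 3 of the genes that fell. CT010467.1, annotated as ribosomal RNA on chromosome 17 (39846353 to 39848827), fell from 1918 ± 356 to 1043 ± 77.4 CPM (SD, n = 3 each; log2 fold change -0.88, SE 0.11, adjusted p = 0.0302, edgeR). Lars2, the mitochondrial leucyl-tRNA synthetase, fell from 399 ± 80.0 to 181 ± 17.8 CPM (log2 fold change -1.14, SE 0.13, adjusted p = 0.0137), and Gm23935, annotated as a microRNA, had a log2 fold change of -1.13 (SE 0.12, adjusted p = 0.010). Genes annotated as ribosomal RNA took 0.189% ± 0.0363 of counts in wild type and 0.106% ± 0.00615 in knockout libraries (SD, n = 3 each). Nearly all of these counts were those of CT010467.1, so this share repeats its fall and is not a separate result. With a robust prior, added after the data had been seen, none of these 3 genes was called. None of them was called without knockout replicate 2 or without knockout replicate 3, and CT010467.1 was also not called without wild type replicate 2 or among genes with a mean of at least 10 CPM.

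The 2 genes that rose were Qpct and F630028O10Rik. Qpct, glutaminyl-peptide cyclotransferase, went from 19.1 ± 1.26 to 26.9 ± 1.23 CPM (SD, n = 3 each; log2 fold change 0.49, SE 0.07, adjusted p = 0.0371, edgeR). F630028O10Rik (X chromosome, 96239926 to 96243636), a noncoding transcript that spans the microRNA gene Mir223, went from 51.2 ± 1.78 to 65.4 ± 0.381 CPM (log2 fold change 0.35, SE 0.05, adjusted p = 0.0302). It lies beside Vsig4 (96247203 to 96293438) on the opposite strand. F630028O10Rik was called in none of the 6 fits without 1 library and Qpct in 1 of them. The call of F630028O10Rik also ended with the replicate block (adjusted p = 0.0559), and those of F630028O10Rik (0.0527) and Qpct (0.0674) ended among genes with a mean of at least 10 CPM. S100a8, a calcium-binding protein abundant in neutrophils, had a log2 fold change of 0.70 (SE 0.10) and missed the threshold at an adjusted p of 0.0521. It was called in 9 of 19 alternatives, among them library totals, the DESeq2 test, limma-voom, the replicate block and bias-corrected dispersions (adjusted p = 0.0468), with adjusted p-values from 7.36e-15 without a filter to 0.329 with a robust prior. At an unadjusted p under 0.05, 326 genes were higher and 413 lower, against 679 in all expected by chance; with library totals alone as the scaling, the balance turned to 768 higher and 243 lower.

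The libraries also differed in a way that genotype did not explain. The first principal component, with 29.3% of the variance, placed knockout replicate 1 at 2.62 and wild type replicates 1 and 2 at 19.9 and 17.5, and knockout replicates 2 and 3 at -17.4 and -13.2 with wild type replicate 3 at -9.41. When the libraries were split along this line instead of by genotype, 522 genes passed the same test, against 14 for genotype. This split was singled out as the one with the most genes among the 9 other splits, so its count is a selected maximum. The remaining 8 gave 0 to 2 genes each. The labels give no batch that matches this split. The second component, with 20.6% of the variance, placed the knockout libraries at 15.1, 3.66 and 8.80. All of them lay above the wild type libraries, at -4.89, 0.911 and -23.5.

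**Figure D2:**
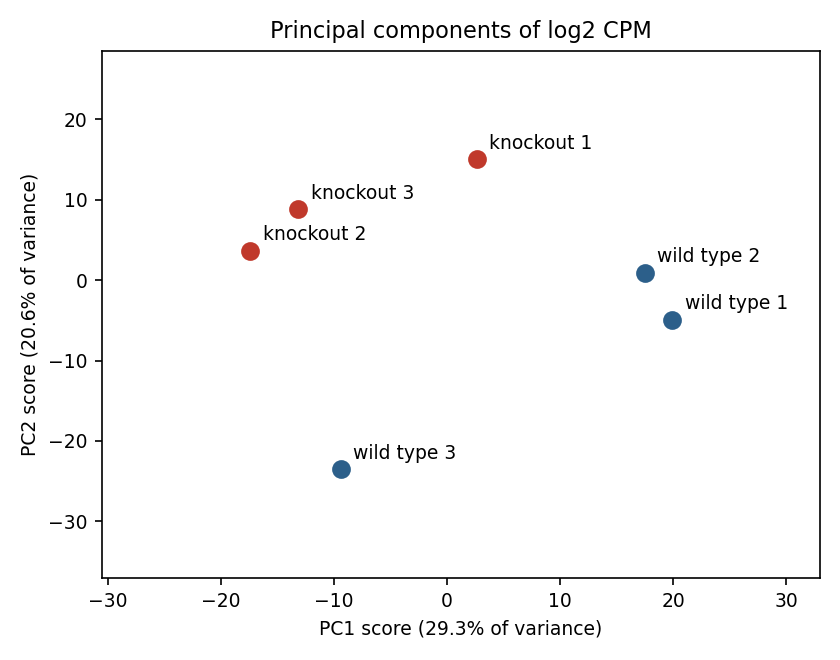
Principal component scores of the 6 libraries from log2 CPM, with knockout libraries in red and wild type libraries in blue, each numbered by replicate. The first component (29.3% of variance) and the second (20.6%) both place wild type replicate 3 away from wild type replicates 1 and 2. On the second component all knockout libraries lie above all wild type libraries.

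Of the 36 gene lists tested, 12 passed camera with a preset correlation, 9 lower and 3 higher in knockout. None of them passed with an estimated correlation, where the lowest adjusted p was 0.322, or with fry's test of movement in one direction, where it was 0.408; at an unadjusted p under 0.05, 5 and 3 lists did. Fry's test of change in either direction passed 3 of the 36 lists: matrix remodelling and motility (adjusted p = 0.000114), which holds Vcam1, alternative activation (0.00771), which holds Timd4, and potassium channels (0.0193). Between 6 and 12 lists also passed the preset test in 8 of the other splits of the libraries, and 25 in the split along the first component. By the mean of a list's members in each library, 7 of the 12 lists did not separate the genotypes and instead set knockout replicate 1 and wild type replicates 1 and 2 apart from the other 3 libraries, as the first component does. These were the lists of mast cell, erythroid and dendritic cell markers, LXR targets, oxidative phosphorylation, cholesterol biosynthesis and interferon-stimulated genes. MHC class II genes, phagocytic receptors and markers of T, B and NK cells separated the genotypes, and neutrophil markers and matrix genes followed neither line. Separation here means only that the list means did not overlap, with no margin asked. For MHC class II genes, knockout replicate 1 (0.0454) lay just below wild type replicate 1 (0.0544) and apart from knockout replicates 2 and 3 (-0.295 and -0.126). For mast cell markers, wild type replicate 3 (0.115) lay closer to knockout replicate 1 than to knockout replicates 2 and 3 (-0.497 and -0.515). Single members also moved with single libraries: without knockout replicate 2, Apoe went from -0.29 to -0.15, H2-Ab1 from -0.40 to -0.26 and C1qa from -0.18 to -0.10. The list results below are therefore descriptions of small shifts, with members that mostly did not pass on their own.

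Genes of MHC class II antigen presentation lay lower in knockout: all 14 tested members had a negative log2 fold change, with a median of -0.24 (camera adjusted p = 5.64e-09; adjusted p = 0.331 with an estimated correlation). In edgeR's test none of the 14 passed over all genes, and 6 were lower when adjusted over the list alone. Ciita was called lower by the DESeq2 test (adjusted p = 0.00722) and with the split along the first component as a term (0.036; the added split, chosen after the data had been seen), and Ciita, Cd74, H2-Aa, H2-Ab1, H2-Eb1 and H2-DMa without a filter. Ciita, the transactivator of class II genes, had a log2 fold change of -0.37 (SE 0.08), H2-Ab1 of -0.40 (SE 0.13), H2-Eb1 of -0.40 (SE 0.13) and H2-DMa of -0.26 (SE 0.08). Without a filter the log2 fold change of H2-Ab1 was -0.39, but its adjusted p in edgeR's test went from 0.795 to 3.14e-05. Calls made only without a filter are therefore weak support for any gene named here. Markers of dendritic cells, a list that includes Ciita, H2-Ab1 and H2-Eb1, had a median of -0.37 over 16 members (camera adjusted p = 9.78e-06; adjusted p = 0.322 with an estimated correlation), which was -0.23 with the added split as a term. In edgeR's test none of its members passed over all genes and 1 was lower adjusted over the list alone. Ciita was called as above, and without a filter so were H2-Ab1, H2-Eb1, Fscn1 and Siglech; Fscn1, an actin-bundling protein of mature dendritic cells, had a log2 fold change of -0.43 (SE 0.16).

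Lists of markers of other marrow cells had medians in both directions, and none of them passed with an estimated correlation. Neutrophil markers lay higher, with a median of 0.29 over 17 members, 12 positive and 5 negative (camera adjusted p = 1.19e-05; adjusted p = 0.322 with an estimated correlation). In edgeR's test none passed over all genes, while 4 were higher and 1 lower adjusted over the list alone. The DESeq2 test called S100a8 (adjusted p = 2.21e-09), S100a9 (1.49e-06) and Lcn2 (0.00323) higher and Mpo (0.00702) lower, and S100a9 was also called with the replicate block (0.0297). Without a filter, Ngp, Mmp9, Ltf and Mmp8 were called besides these 4, and S100a8, S100a9 and Mpo were called with the added split as a term and with the surrogate variable. S100a9 had a log2 fold change of 0.61 (SE 0.11) and Lcn2 of 0.53 (SE 0.12), whereas Mpo, the myeloperoxidase of early granulocytes, had one of -0.76 (SE 0.18). The median of this list was 0.17 without wild type replicate 2, 0.18 with the added split as a term and 0.14 over the 14 members not shared with another list (camera adjusted p = 0.00595). Erythroid and megakaryocyte markers had a median of -0.52 over 6 tested members (camera adjusted p = 9.78e-06; adjusted p = 0.412 with an estimated correlation), with none called by edgeR either way; Itga2b and Ppbp were called without a filter. The platelet genes Itga2b, Ppbp and Gp9 stood at -0.53 (SE 0.19), -0.52 (SE 0.21) and -0.50 (SE 0.19) and the erythropoietin receptor gene Epor at -0.74 (SE 0.30); the list's median was -0.34 without wild type replicate 1. Markers of mast cells, basophils and eosinophils had a median of -0.50 over 11 members (camera adjusted p = 1.31e-05; adjusted p = 0.395 with an estimated correlation); in edgeR's test none passed over all genes and 2, Cpa3 and Prss34, were lower adjusted over the list alone. Prss34 and Prg2 were called with the surrogate variable, Prss34 with the added split and all 3 without a filter, and the median was -0.93 without knockout replicate 1. Markers of T, B and NK cells had a median of -0.36 over 11 members (camera adjusted p = 0.000418; adjusted p = 0.322 with an estimated correlation). In edgeR's test none passed over all genes and 4 were lower adjusted over the list alone: the B cell genes Ms4a1, Cd79a and Pax5 at -1.36 (SE 0.31), -1.01 (SE 0.33) and -0.87 (SE 0.29), and Cd4 at -0.52 (SE 0.16). Ms4a1 was called with the added split (adjusted p = 0.036), and Ms4a1 and Cd4 were called without a filter. Ms4a1, Cd79a and Pax5 lay at 2.08 CPM or below on average in either group. Epor, at 1.15 CPM in knockout and 1.91 CPM in wild type, and Cpa3, at 1.48 and 2.90 CPM, were low as well.

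Among the functional lists, phagocytic and scavenger receptors had a median of -0.08, with 26 of 30 members negative (camera adjusted p = 2.81e-05; adjusted p = 0.322 with an estimated correlation). Timd4 was the 1 member called by edgeR, and 2 members were lower adjusted over the list alone, Timd4 and Colec12, a scavenger receptor, at -0.49 (SE 0.10). Colec12 was called lower by the DESeq2 test (adjusted p = 0.00619), with the replicate block (0.0255), with the added split (0.0387) and without a filter, and C3 with the added split (0.0309). C1qa, a subunit of complement C1q, had a log2 fold change of -0.18 (SE 0.08) and Fcgr2b, the inhibitory IgG receptor, of -0.23 (SE 0.10). The median of the list was -0.027 without knockout replicate 2, -0.029 with library totals and -0.037 with the added split, and the list passed in all 3 cases. LXR targets and lipid handling genes had a median of -0.12 over 20 members (camera adjusted p = 0.000561; adjusted p = 0.539 with an estimated correlation), with none called by edgeR either way; Apoe, called only without a filter, had a log2 fold change of -0.29 (SE 0.15), Apoc1 of -0.99 (SE 0.32), Abcg1 of -0.20 (SE 0.10) and Mylip of -0.21 (SE 0.09). Expression of Apoc1 was low, at 0.51 CPM on average in knockout and 1.02 CPM in wild type libraries. With the added split as a term the median of the list was -0.045 and the list did not pass (camera adjusted p = 0.0807). Without knockout replicate 2 it was -0.06 and the list did not pass (camera adjusted p = 0.0761); it was -0.24 without knockout replicate 1 and -0.075 without wild type replicate 2. Matrix remodelling and motility genes had a median of -0.04 over 27 members (camera adjusted p = 0.00124; adjusted p = 0.322 with an estimated correlation). Vcam1 was the 1 member called by edgeR and the 1 lower member adjusted over the list alone, and the list no longer passed without it. It also did not pass with limma-voom (camera adjusted p = 0.23) or without wild type replicate 1 (0.0583), where its median was 0.00074; with library totals the median was 0.0033 while the test stayed negative, without knockout replicate 3 it was -0.0029 and with the added split -0.016. Mmp13 and Mmp9, both matrix metalloproteinases, stood at -0.56 (SE 0.15) and 0.39 (SE 0.13), and Thbs1 at -0.29 (SE 0.09). Thbs1 was called with the surrogate variable (adjusted p = 0.0128), and Thbs1, Mmp9, Mmp8 and Mmp12 were called without a filter.

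Nuclear genes of oxidative phosphorylation had a median of 0.04, with 37 of 49 members positive (camera adjusted p = 0.00906; adjusted p = 0.844 with an estimated correlation), and none called by edgeR either way; Ndufa1 and Ndufa8, subunits of respiratory complex I, stood at 0.25 (SE 0.06) and 0.14 (SE 0.05), and Ndufa1 was called with the added split (adjusted p = 0.036). This list did not pass without knockout replicate 3 (median 0.019, camera adjusted p = 0.0948), without wild type replicate 1 (median 0.024, 0.144) or without wild type replicate 2 (median 0.034, 0.0731), nor with the added split as a term (median 0.021, 0.192), and its median was 0.085 with library totals. Cholesterol biosynthesis genes had a median of 0.08, with 20 of 23 members positive (camera adjusted p = 0.0257; adjusted p = 0.937 with an estimated correlation) and none called under any alternative. Fdps, farnesyl diphosphate synthase, stood at 0.59 (SE 0.25) and Dhcr7, the last enzyme of the pathway, at -0.17 (SE 0.09). Expression of Fdps was low, at 1.62 CPM on average in knockout and 1.08 CPM in wild type libraries. The cholesterol list did not pass without knockout replicate 2 (median 0.016, camera adjusted p = 0.832), without knockout replicate 3 (median 0.044, adjusted p = 0.469), without wild type replicate 1 (median 0.044, adjusted p = 0.542) or without wild type replicate 2 (median 0.067, adjusted p = 0.213). It also did not pass with limma-voom (adjusted p = 0.0566), among genes with a mean of at least 10 CPM (0.0508) or without its member of smallest p (0.0606), and with the added split its median was -0.021. Its median was 0.13 with library totals, 0.21 without knockout replicate 1 and 0.18 without wild type replicate 3. Interferon-stimulated genes had a median of -0.11, with 33 of 39 members negative (camera adjusted p = 0.0103; adjusted p = 0.937 with an estimated correlation) and none called by edgeR either way. The median of this list turned to 0.03 without knockout replicate 1 and to 0.04 without wild type replicate 3, where the list did not pass (camera adjusted p = 0.0619 and 0.342). It was -0.061 with library totals and -0.20 without knockout replicate 2 or without wild type replicate 1. With the split along the first component as a term, added after the data had been seen, it was -0.25 (camera adjusted p = 1.05e-46), and Ifit2, Ifit3, Gbp5, Stat2, Ifi204 and Oas3 were among the genes then called lower.

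**Figure D3:**
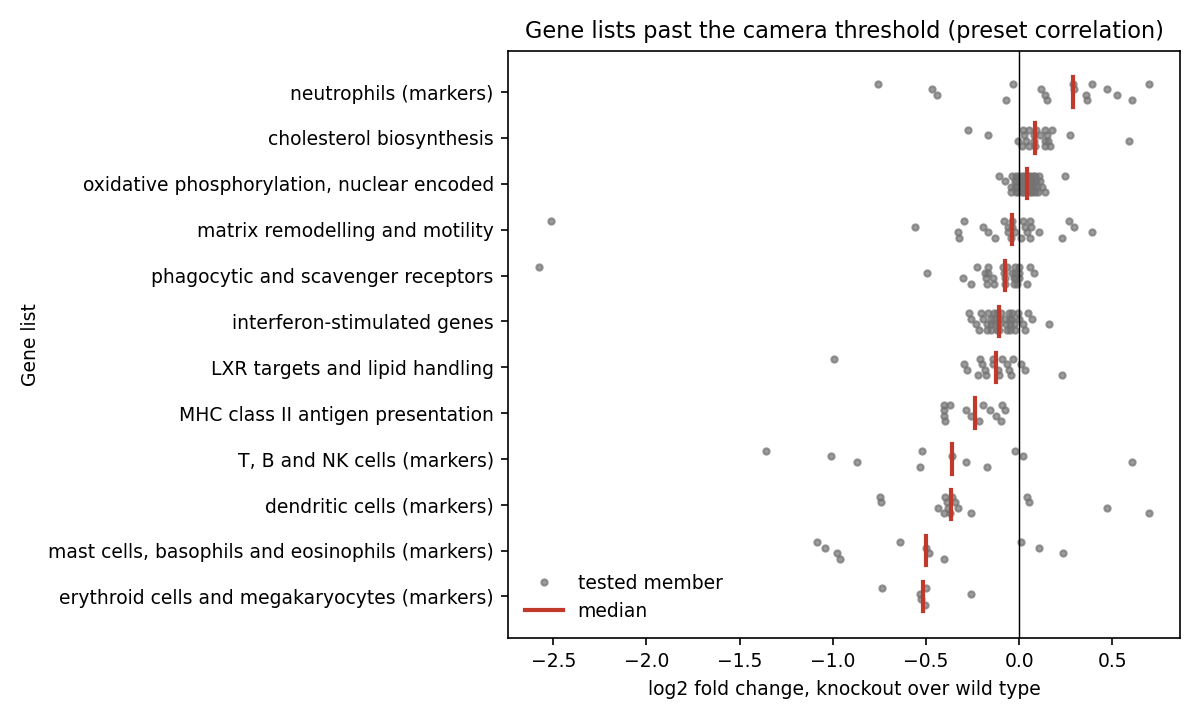
Log2 fold change of knockout over wild type for the tested members of the 12 gene lists that passed camera with a preset correlation; grey points are genes and red bars are list medians. Medians ran from -0.52 for erythroid and megakaryocyte markers to 0.29 for neutrophil markers, and none of the 12 lists passed with an estimated correlation.

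The lists closest to the function of TMEM175 did not pass. Lysosomal hydrolases and membrane proteins had a median log2 fold change of 0.01 over 54 members (camera adjusted p = 0.824), V-ATPase subunits of 0.04 over 17 (0.281), endolysosomal channels and transporters of -0.03 over 28 (0.394) and autophagy genes of 0.01 over 39 (0.156). None of their members was called by edgeR's test. The largest departure by p among lysosomal genes was Hgsnat, named after its value was seen, an enzyme of heparan sulfate breakdown, at -0.42 (SE 0.09, adjusted p = 0.344); it was called lower by the DESeq2 test (adjusted p = 0.00212), with the replicate block (0.0114), with the added split as a term (0.0347) and without a filter, and Slc15a3, an endolysosomal transporter, with the surrogate variable (0.048) and without a filter. Macrophage identity genes had a median of 0.01 over 23 members (camera adjusted p = 0.916), inflammasome genes of 0.01 over 19 (0.824), inflammatory cytokines and chemokines of -0.03 over 38 (0.175) and the neighbours of Tmem175 on chromosome 5 of 0.04 over 13 (0.513). Over the 24 lists that did not pass, medians ran from -0.17 for stromal markers to 0.05 for the NRF2 response and camera adjusted p-values from 0.134 for potassium channels to 0.916. The median and mean differed in sign for lysosomal genes, the Tmem175 neighbours, iron handling, the ATF4 response and the mitochondrially encoded genes, all of them close to 0.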

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

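Bias-corrected dispersions, the robust prior, reduced lists, the term for another split and the surrogate variable were chosen after the data had been seen. The comparison gave 2 genes higher and 12 lower; upper-quartile scaling and DESeq2 size factors gave 2 and 12, library totals, limma-voom and bias-corrected dispersions 3 and 12 each, the robust prior 2 and 11, and a filter of 1 CPM in 3 libraries 2 and 11. The DESeq2 Wald test gave 10 higher and 30 lower, and no filter on low counts 39 and 112 among 25959 genes tested; a mean of at least 10 CPM gave 0 and 5 among 8247, and an added fold change threshold of 1 on the log2 scale gave 0 and 10. A term for the split along the first component gave 16 and 62, and 1 surrogate variable 12 and 32. Those 2 terms were taken from the same counts that were then tested, so the larger numbers are not a better estimate. Without a filter, adjusted p-values in edgeR's test also fell far at near-equal fold changes, for Tmem175 from 6.01e-05 to 1.48e-25. The larger numbers of that setting are thus not a better estimate either. Apart from the smaller gene sets under a filter, the cause of these differences was not tested. All 14 genes were called under each scaling, DESeq2, limma-voom, no filter, bias-corrected dispersions, the added split and the surrogate variable.

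Leaving out 1 library in turn gave 0 to 2 genes higher and 4 to 10 lower, with 4 to 8 of the 14 genes called. Without knockout replicate 2 the counts were 0 and 5, without knockout replicate 3 they were 0 and 4, without wild type replicate 1 they were 0 and 7, without wild type replicate 2 they were 0 and 6 and without wild type replicate 3 they were 2 and 7. Libraries with the same replicate number did not deviate together, with correlations of deviations of 0.06, -0.12 and 0.04. Those with different numbers ran from -0.17 to 0.14. This gave no sign that the numbers pair the samples but cannot exclude it. Knockout and wild type replicate 1, on the same side of the split along the first component, had only 0.06. The replicate block gave 3 genes higher and 14 lower, 11 of them among the 14; F630028O10Rik, Rims3 and Vsig4 lost their calls.

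The count of 12 lists was 8 to 14 under the other scalings, filters and terms and 11 to 16 without 1 library, but 0 with an estimated correlation and 0 with fry. The median of interferon-stimulated genes ran from -0.20 (without wild type replicate 1) to 0.04 without 1 library, turning to 0.0323 without knockout replicate 1 and to 0.0382 without wild type replicate 3, and that of cholesterol biosynthesis to -0.0209 with the added split as a term. That term also ended the calls of LXR targets (median -0.045, adjusted p = 0.0807) and oxidative phosphorylation (median 0.021, adjusted p = 0.192), and took interferon-stimulated genes to -0.25. The cause was not tested. Some calls rested on few reads: Paqr9 had 2 to 4 counts per knockout library. The effect of depth was not tested.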

Other observations

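The tests of linked variants, of the split as a term, of ribosomal RNA in Lars2 and of reads shared by Lyz1 and Lyz2 were chosen after the results were seen, as were the 3 patterns; the others were set before their values were seen, except that 4 of the resident macrophage markers had been seen before that test was run, and that the margins of error asked of each bound were set afterwards. Genes named here for the first time were chosen after their values were seen.

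Potassium channels other than Tmem175 had a median log2 fold change of -0.01 over 12 members, and none was called by edgeR. When adjusted over the list alone, 2 were lower: Kcna2, a voltage-gated channel, at -1.52 (SE 0.31) and Kcnj10, an inward rectifier, at -0.38 (SE 0.09). Kcna2 was called lower by the DESeq2 test (adjusted p = 0.00212), with the added split (0.0151) and with the surrogate variable (0.0209), and both were called without a filter. In the alternative activation list, Timd4 was called by edgeR and Chil3, a chitinase-like protein of alternatively activated macrophages, stood at 0.33 (SE 0.07), higher when adjusted over the list alone and called by the DESeq2 test (adjusted p = 0.0352), without a filter, with the added split and with the surrogate variable. Slco2b1, an organic anion transporter, had a log2 fold change of -1.18 (SE 0.19, adjusted p = 0.102, edgeR), and Cd5l, a secreted protein of tissue macrophages, one of -0.54 (SE 0.10, adjusted p = 0.157); both were called lower by the DESeq2 test (1.35e-06 and 3.27e-05), without a filter, with the added split and with the surrogate variable, and Slco2b1 also with the replicate block (0.0382) and without knockout replicate 1.

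Vcam1, Epb41l3, Paqr9, Itgad, Timd4, Rims3 and Vsig4 were lower in knockout, and several are known from resident macrophages of tissues. None of the 7 lies within 20 Mb of Tmem175 or Lyz2 (0 genes), which argues against local effects of variants linked to either allele. Variants elsewhere, or acting at a distance, would not show in that count. With the split along the first component as a term, 7 of 7 stayed below an adjusted p of 0.05. This decides nothing about that split, since the 7 had been chosen for their genotype difference. All 14 called genes stayed called with that term. Fewer resident-macrophage-like cells in the knockout wells may still contribute: 19 other markers had a median log2 fold change of -0.17 (SE of the median 0.07), or -0.18 without the 4 seen before, and 4 of the 19, Spic, Stab2, Fcna and Crip2, were lower at an unadjusted p under 0.05 and 0 were higher. Both medians lie above the bound of -0.25 set in advance for markers not looked at, so this would have been argued against without the margin of 2 SE, which was set afterwards and leaves it open. Abundant markers such as Siglec1, at 542 ± 27.7 CPM in knockout and 615 ± 92.6 CPM in wild type (SD, n = 3 each), would hide a small share of such cells, so this cannot be told apart from a change within the cells.

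Lars2 was lower together with ribosomal RNA features, while Gm26917, a noncoding transcript beside CT010467.1, stood higher at 0.28 (SE 0.06, adjusted p = 0.303, edgeR) and was called by the DESeq2 test (0.0495), with the added split (0.0293) and without a filter. A shared change of mitochondrial tRNA synthetases is argued against by a median log2 fold change of -0.015 over the other 16 genes of that class (SE of the median 0.02). Ribosomal RNA reads counted to Lars2 were searched for as a match of at least 50 bases to CT010467.1, and 0 of 9 Lars2 transcripts held one. That bound had been set badly, since the RefSeq table places a small-subunit ribosomal gene, Rn18s-rs5, at this position, and large-subunit sequence would not be found by it. A later search found 72 bases of Lars2 at 98.6% identity to Gm15564. Gm15564, annotated as an antisense transcript on chromosome 16, stood at -1.12 (SE 0.23, adjusted p = 0.28, edgeR). Whether it holds large-subunit sequence was not tested. The searches listed no match of Gm23935 to Lars2 or CT010467.1. Deviations of Lars2 and CT010467.1 from their group means had Pearson's r = 0.895 (exact permutation p = 0.139) over 6 libraries. Spearman's rho was 0.829 (exact permutation p = 0.139). Without the 2 libraries farthest in CT010467.1, r was 0.0637, but leaving out extreme values lowers a correlation by itself. Lars2 had the same order of libraries as Gm23935 in each group. In knockout libraries Lars2 stood at 200, 178 and 165 CPM and Gm23935 at 324, 291 and 284 CPM. In wild type libraries they stood at 491, 365 and 342 CPM and at 803, 602 and 565 CPM. Ribosomal RNA reads counted to Lars2 cannot be told apart from a change in Lars2 itself.

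Lyz1, which lies beside Lyz2 and resembles it closely, had a log2 fold change of 1.36 (SE 0.28, adjusted p = 0.303), with 180, 77.8 and 81.5 CPM in knockout against 47.3, 43.0 and 41.7 CPM in wild type libraries; knockout replicate 1 stood highest. Without that library the value was 0.86; Lyz1 was called higher in that fit, without a filter, with the added split and with the surrogate variable. The test of reads shared between Lyz1 and Lyz2 was the log2 fold change of Lyz1, 1.36, which is part of the pattern itself. A constant share of Lyz2 reads counted to Lyz1 would have lowered Lyz1 along with Lyz2. Lyz1 was instead higher in every knockout library, which argues against such a constant share as the source of its rise. A share that differed between the groups stays open and cannot be told apart from a change in Lyz1. Variants or cis effects around the Cre allele may play a part: 5% of the 20 other tested genes within 2 Mb of Lyz2 had an unadjusted p under 0.05, below the bound of 10% set in advance, so this would have been argued against without the exact binomial interval (95%, 0.127% to 24.9%), which was asked for afterwards and leaves it open, and an effect on Lyz1 alone would not show in that share. The genotype itself, which includes the Cre insertion in Lyz2, stays open as an untested cause of all 3 patterns. For Lyz2, the label Lyz2-Cre+/- gives the insertion on 1 allele, and 53.8% of the wild type level remained in knockout libraries.

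With 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real split gave 2 genes higher, 12 lower and 12 lists. Counting either direction, 2 of the 10 splits, the real one included, had as many genes as the 2 higher and 2 as many as the 12 lower, with 281 the highest other count for both; 4 had as many lists, with 25 the highest other. The split with 522 genes, several times the real count, was picked as the highest of the 9 other splits, and the remaining 8 gave 0 to 2 genes each. It points to a structure of the samples that the labels do not name.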
